A study of Drosophila melanogaster with 9 samples.

How the data were processed

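The samples were dissected central nervous systems of homozygous 1st instar larvae raised at 25 °C, per the labels' protocols, in 3 genotypes with 3 libraries each: Canton-S, elav5 and elav5/fne. Libraries were made with the Lexogen QuantSeq REV kit, which reads transcripts from their 3' ends, from 40 ng of total RNA, and the genome build was dm6, per the labels. The aligner, the counting program, the annotation and its strand setting are not given in the sources used here. 1 table was used, with 17421 FlyBase genes as rows and the 9 libraries as columns. The deposited values are a signal in which each library's whole read counts per gene were divided by 1 size factor per library; this was read from the values, all of which are whole multiples of their column's smallest step within 0.1. The file's name calls them CPM, but the deposited column totals lie between 15.67 and 18.47 times 1e6.

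All values were multiplied by 1e6 over the mean deposited column total, which keeps the deposited scaling between libraries, and are called normalised CPM. Reads recovered by multiplying out the size factor numbered 15241461 to 18822734 per library, and 3 reads corresponded to 0.150 to 0.196 normalised CPM. Gene IDs were joined to symbols and coordinates of the BDGP6.54 annotation; 17251 matched and 170 did not, with 2.57% to 4.08% of each library's total, and 104 of the latter were tested under their ID. Of 137 genes named by rule, 46 overlap another annotated gene and 17 of these on the same strand, so with an unknown strand setting their reads may include those of the neighbour, and reads of close gene copies may be shared.

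The design was written before the data were examined and assumed CPM per 3' end. As the table holds 1 value per gene, the planned tests of single 3' ends, of the distal to proximal ratio, of the share of genes shifted to the proximal end and of U-rich sequence could not be made, and a genome sequence was not used here. The planned gene test was kept: limma 3.58.1 with a trend on log2(normalised CPM + 1), in 1 fit over all 9 libraries by genotype alone, for genes with a mean of at least 1 (9384 genes), with Benjamini-Hochberg adjustment and an adjusted p under 0.05. Changes were called higher or lower by the sign of the contrast, and elav, fne and Rbp9 were given for every genotype with exact permutation tests. In 28 gene lists written beforehand, 8 entries had no match, members were counted over all genes and adjusted over the list alone, and lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01. The estimated correlation was the alternative.

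The lists were ELAV/Hu family, other neuronal RNA-binding proteins, cleavage and polyadenylation factors, known ELAV splicing targets, genes with known neural 3' UTR extensions, synaptic genes, neurotransmitter genes, ion channels, neuropeptides, axon guidance, neuroblast, glial, cell cycle, apoptosis, heat shock, detoxification, immune, ribosomal protein, glycolysis, oxidative phosphorylation, dosage compensation and sex, ring gland, muscle, gut, fat body, hemocyte, salivary gland, and cuticle, epidermis and trachea genes. Named genes were chosen by rule: per mutant, among called genes with a mean of at least 10 and no overlap between libraries, the 10 largest rises and falls, for elav5/fne against elav5 the 5 largest, and up to 4 members of each list with the smallest p in elav5/fne against Canton-S. The rule for 3' ends could not be applied. Genes in the closing part that fall outside the rule were chosen after their values were seen.

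Alternatives were pseudocounts of 0.25 and 5, other filters, robust eBayes, the replicate number as a block, fits over 2 genotypes, TMM and median of ratios scaling, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, and each library left out in turn. Added after the data were seen were the removal of elav5 replicate 1 and elav5/fne replicate 3, the muscle list level as a covariate, scaling to the library total and a pseudocount of 1 in the deposited unit. The pipeline was tested on simulated data: for elav5/fne against Canton-S, 82% of 50 genes changed 8-fold, 74% of those changed 4-fold, 18% of those changed 2-fold and 6% of those changed 1.5-fold were recovered, and 2 of 9184 unchanged genes were called. Correlation and covariance of both mutants' changes were set beside 100 simulated draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used.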

Results

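Reads from the 3' ends of transcripts were counted per gene in the dissected central nervous system of 1st instar Drosophila larvae, the stage that hatches from the egg. Canton-S, a common wild-type strain, was compared with elav5 larvae, which carry a deletion allele of elav, and with elav5/fne larvae, which carry deletions of both elav and fne. Both genes encode ELAV/Hu proteins, neuronal RNA-binding proteins that act on splicing and on the choice of 3' end. Each genotype had 3 libraries, and an fne single mutant was not analysed here. Libraries held between 15241461 and 18822734 reads assigned to genes, and between 10712 and 11970 genes had at least 1 read. Levels are given as normalised CPM with the mean ± SD and n = 3, and changes as log2 fold changes on the log2(normalised CPM + 1) scale, which understates the change of low genes. The labels do not state whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The depth set a floor of 3 reads, which corresponded to between 0.150 and 0.196 normalised CPM, and floors cover counting error only.

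The transcripts of the deleted genes were low in the genotypes labelled as their mutants. elav (chromosome X, 509235 to 523226, dm6) was at 1643 ± 68.3 normalised CPM in Canton-S, 31.2 ± 9.26 in elav5 and 45.3 ± 22.6 in elav5/fne, which is 1.90% and 2.76% of the Canton-S mean. fne (chromosome X, 12917477 to 12950417) was at 5041 ± 546 in Canton-S and 4696 ± 219 in elav5, and at 375 ± 129.8 in elav5/fne, 7.44% of the Canton-S mean. On the log2 scale elav fell by 5.72 in elav5 (SE 0.31, limma adjusted p = 1.5e-05) and by 5.25 in elav5/fne (adjusted p = 2.44e-06), and fne fell by 3.79 in elav5/fne (SE 0.20, adjusted p = 1.61e-06). fne did not pass the test in elav5 (log2 -0.10, adjusted p = 0.767). Rbp9, the remaining ELAV/Hu gene of the fly, was low, at 2.67 ± 0.814, 5.56 ± 1.93 and 5.07 ± 2.40 normalised CPM, and did not pass the test in either mutant (adjusted p = 0.128 and 0.125). Exact permutation tests, 2-sided, gave p = 0.1 for elav in both mutants and for fne in elav5/fne, the smallest value that 3 against 3 libraries allow, and p = 0.4 for fne in elav5. Rbp9 likewise gave exact p = 0.1 in elav5, where its mean was 208% of Canton-S, and exact p = 0.2 in elav5/fne. Which part of each gene is deleted is not given in the sources used here, so the source of the remaining reads is open.

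**Figure D1:**
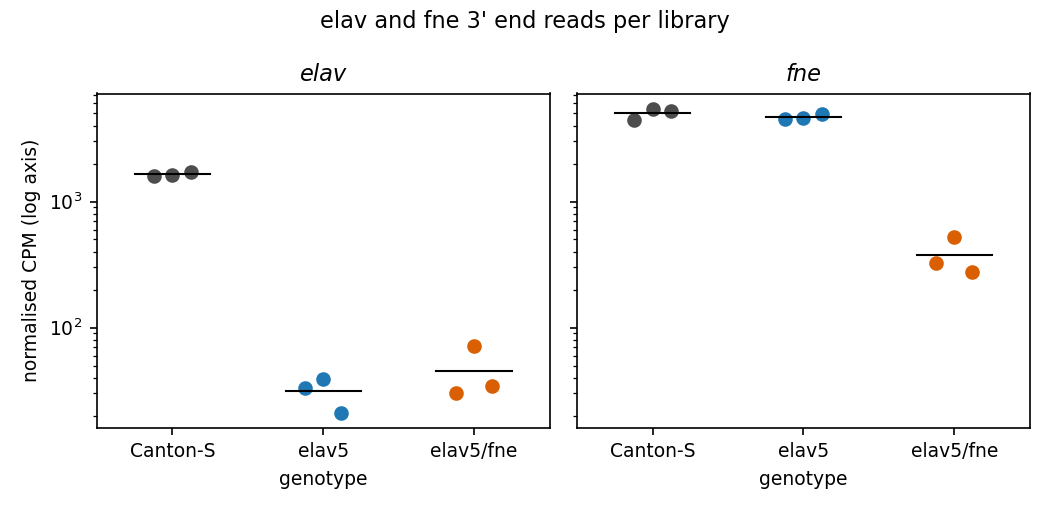
Normalised CPM of elav (left) and fne (right) in each of the 9 libraries, on a log axis, by genotype; points are libraries and lines are means. elav was near 31.2 and 45.3 in the mutants against 1643 in Canton-S, and fne was lower only in elav5/fne.

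Over all tested genes, libraries of the same genotype correlated with r of 0.980 to 0.982 in Canton-S, 0.925 to 0.963 in elav5 and 0.923 to 0.976 in elav5/fne, across genes, which are not independent replicates. The first principal component carried 53.9% of the variance, and elav5 replicate 1 lay apart from the other elav5 libraries on it. Genes of larval muscle and gut, tissues that lie next to the dissected nervous system, differed between libraries of the same genotype. The mean log2 level of the muscle list lay 2.91, 1.15 and -0.25 from the Canton-S mean in elav5 replicates 1, 2 and 3, and 0.97, 2.13 and 3.10 in elav5/fne replicates 1, 2 and 3. The gut list lay 3.34, -0.75 and -0.32 from the Canton-S mean in elav5 and 0.16, 2.54 and 3.97 in elav5/fne, in the same order. The levels of elav5 replicate 1 and elav5/fne replicates 2 and 3 were thus the highest for both lists, and counts without elav5 replicate 1 and elav5/fne replicate 3 are given beside each comparison.

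**Figure D2:**
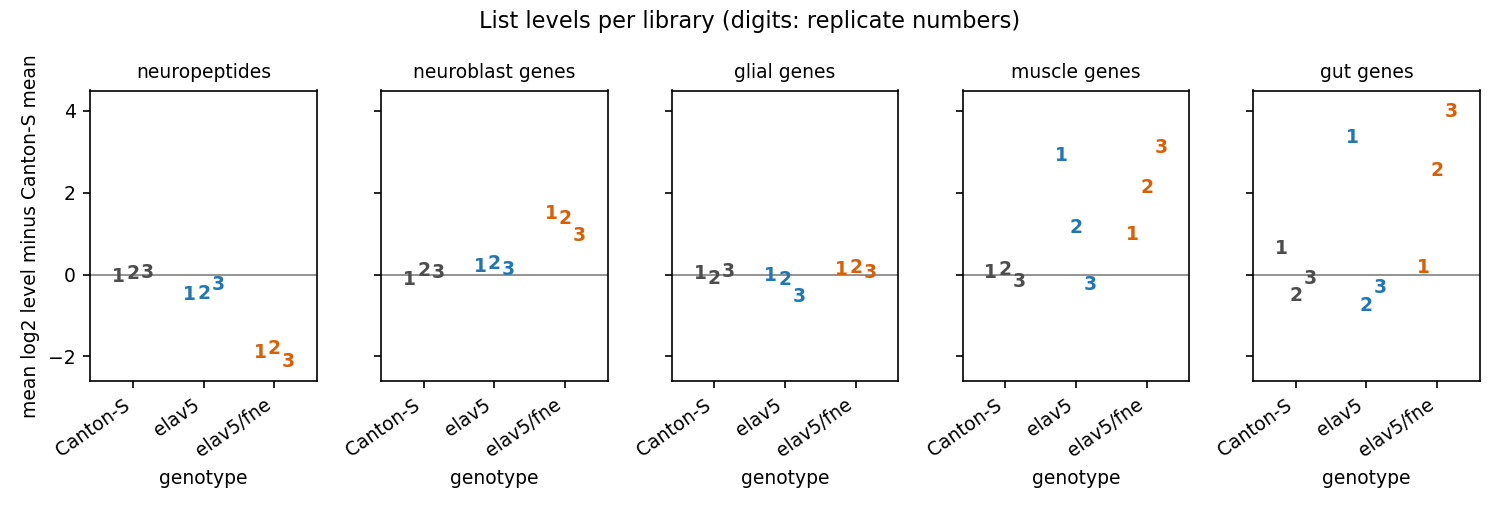
Mean log2 level of 5 gene lists in each library minus the mean of the 3 Canton-S libraries (vertical axis, log2 units), by genotype; digits are replicate numbers. Neuropeptide genes lay between -2.14 and -1.80 in all 3 elav5/fne libraries, whereas the muscle list lay between -0.25 and 3.10 in the 6 mutant libraries.

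The first comparison, elav5 against Canton-S, asked what changes when elav alone is lost. Whether the strains share a genetic background is not given in the sources used here. Other differences between the strains therefore cannot be told apart from the loss of elav. The detoxification gene GstD2, the metallothionein genes MtnB, MtnD and MtnE and 70 of 78 ribosomal protein genes were higher in elav5, and the neuropeptide genes Pdf and Orcokinin and 4 of 5 genes of the hormone-producing ring gland were lower. Pdf (chromosome 3R, 26455462 to 26456141), which encodes the circadian pigment-dispersing factor, went from 78.6 ± 2.90 to 10.1 ± 2.07 normalised CPM, and fell by 2.87 on the log2 scale (SE 0.28). GstD2, a detoxifying glutathione S-transferase, rose from 3.62 ± 2.595 to 98.0 ± 45.6 (log2 4.43, SE 0.53). In all, 1428 of 9384 tested genes passed an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 767 higher and 661 lower, and 337 of the higher and 202 of the lower genes changed by over 2-fold. The count was 706 without Canton-S replicate 1 and 727 without Canton-S replicate 2, and 1235 without elav5 replicate 1 and elav5/fne replicate 3. Scaling each library to its total, a setting in which the median of all genes was -0.12 in place of 0.02, gave 1741 genes, 559 higher and 1182 lower. The libraries of both groups did not overlap for 35.6% of tested genes, where chance gives 10%.

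Of the 10 largest rises in elav5, chosen among genes with a mean of at least 10 normalised CPM and no overlap between libraries, lncRNA:CR40469, a noncoding RNA gene (chromosome X, 122493 to 122706), led with 82.0 ± 98.1 in Canton-S and 22282 ± 4782 in elav5 (log2 8.81). Its log2 change was 7.99 without Canton-S replicate 1 and 9.82 without Canton-S replicate 2. MtnB, MtnD and MtnE, metallothioneins that bind heavy metals, rose from 0.168, 0.0835 and 2.38 to 59.6 ± 28.3, 70.0 ± 22.0 and 127 ± 87.0 (log2 5.63, 5.99 and 5.001). sordd2 rose from 0.104 to 33.5 ± 12.7 (log2 4.91, adjusted p = 0.000111). CG14454 (log2 4.89), CG32453 (4.23), CG18649 (4.03) and CG9759 (3.88) completed the 10 together with GstD2, and among the elav5 libraries each was highest in replicate 1. Without that library CG14454 was at 3.73, CG32453 at 2.96, CG18649 at 3.08 and CG9759 at 2.80, the last no longer past the threshold (adjusted p = 0.0520). CG32453 also lost its call without Canton-S replicate 2 (log2 3.89), CG18649 without Canton-S replicate 1 or 2 (3.61 and 3.83), and CG9759 without Canton-S replicate 1, 2 or 3 (3.87, 4.35 and 3.399).

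Of the 10 largest falls, lncRNA:CR34335 (chromosome X, 3545750 to 3546110, inside DIP-alpha on the same strand) went from 17522 ± 2230.5 to 30.7 ± 2.38 normalised CPM, a fall of 9.11 on the log2 scale (SE 0.33). CG40472 (chromosome 3L, 24927130 to 24927710) went from 96.2 ± 7.79 to 0.348 ± 0.335 (log2 -6.20), and elav was among the 10. Orcokinin, a neuropeptide gene, fell from 57.5 ± 1.68 to 5.46 ± 1.12 (log2 -3.19), and Rab18, a small GTPase of membrane traffic, from 51.0 ± 3.68 to 4.81 ± 0.419 (-3.16). sn, which encodes the actin bundler fascin, fell from 114 ± 8.60 to 14.5 ± 1.36 (-2.89), and Prosbeta6, a proteasome subunit gene, from 83.4 ± 11.4 to 8.12 ± 2.99 (-3.25). CG40472, sn and Prosbeta6 were higher in elav5/fne than in elav5, although elav was low in both mutants. CG11300 (log2 -4.84) and CG34278 (-4.44) varied among Canton-S libraries, with values of -5.80 and -5.26 without Canton-S replicate 2.

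Of 78 ribosomal protein genes 70 rose, none fell and 8 did not pass the test (74 rose adjusted over the list alone). RpL32 rose from 1155 ± 50.8 to 2044 ± 250.3 normalised CPM (log2 0.82) and RpL35 from 1319 ± 29.3 to 2161 ± 188 (0.71). The list median was 0.58 above that of all genes (camera with a preset correlation, adjusted p = 1.33e-32; adjusted p = 0.639 with an estimated correlation). Of 14 detoxification genes 7 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone (median 1.58, like all list medians relative to all genes, adjusted p = 0.00111; adjusted p = 0.639 with an estimated correlation). Beside GstD2, GstE6 rose from 5.97 ± 0.939 to 55.5 ± 16.3 (log2 2.99) and the glycosyltransferase gene Ugt35A1 from 9.81 ± 1.01 to 25.1 ± 3.75 (1.27). With the muscle list level of each library as a covariate the detoxification list no longer passed (adjusted p = 0.0622, range over all settings with the preset correlation 0.000121 to 0.0622). Its level lay 2.06, 1.28 and 0.75 above the Canton-S mean in elav5 replicates 1, 2 and 3, the order of their muscle levels. Carry-over of neighbouring tissue may thus add to this rise. Replicate 3, with a muscle level of -0.25, still lay above every Canton-S library. Of 12 heat shock genes 3 rose and none fell, 7 rose adjusted over the list alone, and the list passed the test (median 1.73, adjusted p = 0.00111; adjusted p = 0.639 with an estimated correlation). The heat shock level lay -1.14, 0.86 and 0.28 from the Canton-S mean in Canton-S replicates 1, 2 and 3. It lay at 2.23, 0.61 and 2.01 in the elav5 replicates, so elav5 replicate 2 was below Canton-S replicate 2. Of 5 ring gland genes, which make ecdysone, juvenile hormone and adipokinetic hormone, 4 fell and 5 fell adjusted over the list alone (median -1.25, adjusted p = 0.000409; adjusted p = 0.639 with an estimated correlation). spok, an ecdysone synthesis gene, fell from 22.6 ± 2.82 to 4.74 ± 1.58 (log2 -2.07) and sad, another, from 4.17 ± 0.609 to 0.518 ± 0.453 (-1.81). Of 27 lists 12 passed, and 0 did with an estimated correlation (adjusted p = 0.639 for each of the 12, and 0 lists with an unadjusted p under 0.05).

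Neuronal lists moved little in elav5. Of 25 neuropeptide and processing genes 6 fell, 1 rose and 18 did not pass, with the same counts adjusted over the list alone (median -0.32, adjusted p = 0.0174; adjusted p = 0.639 with an estimated correlation). Of 16 synaptic genes 4 fell and none rose (median -0.19, adjusted p = 0.0143; adjusted p = 0.639 with an estimated correlation). Rop, a regulator of vesicle fusion, fell from 297 ± 27.0 to 145 ± 17.1 (log2 -1.03), as did the syntaxin gene Syx1A (-0.46). Of 17 ion channel and receptor genes 3 fell (median -0.16, adjusted p = 0.0197; adjusted p = 0.639 with an estimated correlation). nAChRalpha7, an acetylcholine receptor subunit gene, went from 713 ± 38.6 to 393 ± 39.6 (-0.86). Of 12 glycolysis genes 2 fell (median -0.24, adjusted p = 0.0194; adjusted p = 0.639 with an estimated correlation), one being Hex-A, a hexokinase gene (-0.69). Of 18 genes with known neural 3' UTR extensions 4 fell, elav included, and 1 rose (median -0.20, adjusted p = 0.0120; adjusted p = 0.639 with an estimated correlation). Without elav and fne the preset correlation gave 0.0336. mei-P26, a translational regulator, fell from 3088 ± 428 to 1638 ± 239 (-0.92), and lin-28, a regulator of let-7, rose from 23.5 ± 2.76 to 45.6 ± 1.34 (0.93). Counts adjusted over the list alone were the same for these 4 lists. Of 10 apoptosis genes 3 rose and 5 rose adjusted over the list alone (median 0.58, adjusted p = 0.0202; adjusted p = 0.639 with an estimated correlation). Of 18 cell cycle genes 2 fell and 1 rose (3 fell and 1 rose adjusted over the list alone; median -0.33, adjusted p = 0.0367; adjusted p = 0.639 with an estimated correlation). None of the 16 muscle genes passed, with the same count adjusted over the list alone, while the list did (median 1.38, adjusted p = 0.0165; adjusted p = 0.639 with an estimated correlation).

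Of these 12 list calls 7 were lost without 1 library. Without elav5 replicate 1, the library with the highest muscle and gut levels of its genotype, the adjusted p was 0.182 for muscle, 0.221 for glycolysis, 0.0753 for neuropeptides and 0.0658 for synaptic genes. Without elav5 replicate 3 it was 0.0911 for apoptosis, 0.150 for cell cycle and 0.174 for ion channels, and without Canton-S replicate 3 it was 0.0685 for ion channels. Cell cycle genes were also lost without Canton-S replicate 1 (0.0563) and without Canton-S replicate 2 (0.101). Over all settings with the preset correlation the adjusted p ranged over 2.58e-05 to 0.182 for muscle (its own level as a covariate left out), 0.000368 to 0.392 for glycolysis, 0.00212 to 0.208 for neuropeptides, 0.00162 to 0.154 for synaptic genes, 0.00920 to 0.0911 for apoptosis, 0.0173 to 0.150 for cell cycle and 0.00075 to 0.174 for ion channels. The ribosomal protein, ring gland, detoxification, heat shock and 3' UTR extension lists passed without each library in turn. In the remaining 15 lists tested, neuroblast, glial, oxidative phosphorylation and fat body genes among them, the test did not pass. Of these, hemocyte genes passed without elav5 replicate 1 among other settings (range over settings 0.00125 to 0.457), other neuronal RNA-binding proteins without elav5 replicate 2 or without a filter (0.0230 to 0.398), and fat body genes without Canton-S replicate 1 or with the muscle covariate (0.0389 to 0.946). The dosage compensation list held the sex-specific noncoding RNA lncRNA:roX1, which rose from 1488 ± 30.6 to 4132 ± 489 (log2 1.47), and Sxl, the sex-determining splicing regulator, which fell from 907 ± 65.6 to 484 ± 66.1 (-0.91). The sex of the larvae is not given in the sources used here. A different mix of sexes therefore cannot be told apart from an effect of genotype in either comparison against Canton-S. Without subtracting the median of all genes, the median, mean and test differed in sign for known ELAV splicing targets (-0.09, 0.03, lower) and neurotransmitter synthesis and transport (0.04, -0.02, lower); under scaling to the library total the neurotransmitter median was -0.11.

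The second comparison, elav5/fne against Canton-S, asked what changes when both ELAV/Hu genes are lost. Here too, other differences from the Canton-S strain cannot be told apart from these losses. Among the lists that fell were those of neuropeptides, transmitter synthesis and transport, synaptic proteins, ion channels and glycolysis. Lists of neuroblasts, the neural stem cells, of cell death, ribosomal proteins, muscle and heat shock rose. These 10 list calls were made with a preset correlation and were all lost otherwise (adjusted p = 0.339 to 0.621 with an estimated correlation). Ilp2 (chromosome 3L, 9799698 to 9800440), an insulin-like peptide gene, went from 129.7 ± 7.47 to 2.07 ± 1.32 normalised CPM, a log2 change of -5.51 (SE 0.33), and Snap25 (chromosome 3L, 24074180 to 24299205), a SNARE protein of vesicle fusion, from 212 ± 20.4 to 4.71 ± 3.90 (-5.42). ase (chromosome X, 460747 to 463176), a neuroblast transcription factor, went from 4.17 ± 1.79 to 62.3 ± 7.03 (3.67, SE 0.26). In all, 4056 of 9384 genes passed (limma with Benjamini-Hochberg adjustment), 2418 higher and 1638 lower, with 1451 and 609 of them over 2-fold. Libraries of both groups did not overlap for 58.3% of tested genes, where chance gives 10%. The median of all genes was 0.15 here, and it was 0.02 under TMM scaling, a shift of over 0.1. That scaling gave 4210 genes, 2051 higher and 2159 lower, so list medians are again given relative to all genes. The count was 4031 without elav5 replicate 1 and elav5/fne replicate 3.

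Among the 10 largest rises, w (chromosome X, 2790599 to 2796466), an eye pigment transporter gene widely used as a visible marker in fly strains, went from 0.607 ± 0.356 to 233 ± 13.6 normalised CPM (log2 7.21, adjusted p = 5.25e-07). wntD, a secreted signal of the Wnt family, rose from 0.0168 to 38.5 ± 10.8 (5.24), and GstD2 to 168 ± 96.7 (5.19). lncRNA:CR40469 was at 20649 ± 3731 (8.71, and 7.89 without Canton-S replicate 1 and 9.71 without Canton-S replicate 2). LysD, a lysozyme gene with close copies beside it, had no read in any Canton-S library and 66.6 ± 54.4 in elav5/fne, at least 416-fold higher than the floor of 3 reads per library. BomS3, an antimicrobial Bomanin gene, rose to 102 ± 61.2 (5.42) and CG16713 to 213 ± 127 (5.25), and CG17738 (5.58), CG9759 (5.43) and CG9877 (5.20) completed the 10. LysD, CG17738, CG9759 and CG9877 were lowest without elav5/fne replicate 3 (log2 4.75, 4.69, 4.61 and 4.24) and highest without elav5/fne replicate 1 (6.56, 6.58, 6.14 and 6.15). BomS3 was at 6.11 without elav5/fne replicate 1, and each stayed past the threshold. Among the elav5/fne libraries, muscle and gut levels were likewise lowest in replicate 1 and highest in replicate 3. Leaving out libraries in turn therefore cannot tell these rises from carry-over of neighbouring tissue.

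Among the 10 largest falls, Pdf went to 0.552 ± 0.687 normalised CPM (log2 -5.77), Eh, which encodes eclosion hormone, from 67.4 ± 12.1 to 0.597 ± 0.431 (-5.44), and Orcokinin to 1.63 ± 0.909 (-4.53). lncRNA:CR34335 was at 51.2 ± 28.2 (-8.54). FoxP, a transcription factor gene of neurons, fell from 45.2 ± 3.11 to 1.34 ± 1.17 (-4.42). CG42361 fell from 167 ± 34.0 to 6.03 ± 3.50 (-4.67) and Setd3, a methyltransferase gene, from 19.8 ± 1.54 to 0.0179 ± 0.0311 (-4.35). elav, Ilp2 and Snap25 completed the 10, and all of these calls held without each library in turn. Of these 10, CG42361, Ilp2 and lncRNA:CR34335 overlap other annotated genes on the same strand and elav, Setd3 and Snap25 on the other strand, and since the strand setting of the counting is not given in the sources used here, reads of overlapping genes may not be told apart.

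**Figure D3:**
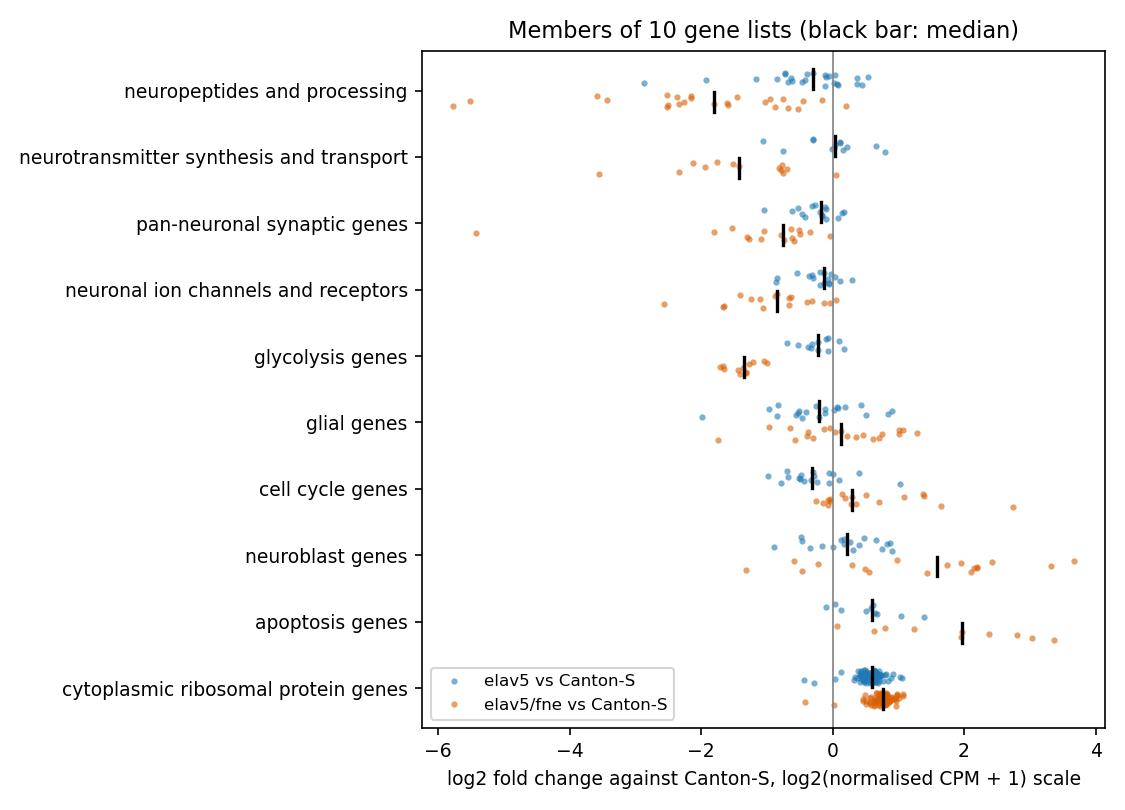
log2 fold change against Canton-S (horizontal axis, log2(normalised CPM + 1) scale) of each tested member of 10 gene lists, in elav5 (blue) and elav5/fne (orange); black bars are list medians. Neuropeptide genes had medians of -0.30 in elav5 and -1.80 in elav5/fne, and neuroblast genes 0.22 and 1.59; the glial median of 0.13 in elav5/fne was -0.01 under TMM scaling.

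Of 25 neuropeptide and processing genes 22 fell in elav5/fne, none rose and 3 did not pass, with the same counts adjusted over the list alone (median -1.95 relative to all genes, adjusted p = 7.17e-15; adjusted p = 0.339 with an estimated correlation). FMRFa fell from 32.2 ± 4.02 to 2.08 ± 0.376 (log2 -3.43) and Dh31, a diuretic hormone gene, from 161 ± 6.90 to 35.4 ± 3.31 (-2.16). Of 13 genes of transmitter synthesis and transport 12 fell and none rose, the same adjusted over the list alone (median -1.57, adjusted p = 9.46e-09; adjusted p = 0.339 with an estimated correlation). Vmat, the vesicular monoamine transporter gene, went from 1107 ± 17.99 to 94.7 ± 20.9 (-3.56), the dopamine transporter gene DAT from 218 ± 4.51 to 50.3 ± 9.92 (-2.12) and ChAT, which makes acetylcholine, from 527 ± 21.6 to 156 ± 20.9 (-1.76). Of 16 synaptic genes 14 fell, and 15 adjusted over the list alone, with none rising (median -0.91, adjusted p = 4.4e-09; adjusted p = 0.339 with an estimated correlation). Beside Snap25, Rop fell to 85.0 ± 12.02 (-1.80), Syx1A from 1609.8 ± 91.0 to 651 ± 46.0 (-1.31) and the complexin gene cpx from 1631 ± 61.4 to 679 ± 69.0 (-1.27). All 12 glycolysis genes fell, also adjusted over the list alone (median -1.49, adjusted p = 1.08e-10; adjusted p = 0.339 with an estimated correlation), with Ldh, lactate dehydrogenase, from 1739 ± 33.5 to 534 ± 80.2 (-1.71) and Hex-A to 560.3 ± 32.9 (-1.67). Of 17 ion channel and receptor genes 13 fell, none rose and 4 did not pass, the same adjusted over the list alone (median -0.99, adjusted p = 4.69e-08; adjusted p = 0.399 with an estimated correlation). slo, a potassium channel gene, fell from 1491 ± 60.8 to 472 ± 34.4 (-1.66) and nAChRalpha7 to 119.6 ± 12.97 (-2.57).

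Genes with known neural 3' UTR extensions, the transcripts whose long neuronal 3' UTRs ELAV/Hu proteins are known to promote, fell in 11 of 18 cases and rose in 2, the same adjusted over the list alone (median -0.66, adjusted p = 0.000297; adjusted p = 0.478 with an estimated correlation). The 11 include elav and fne, and without them 9 of 16 fell (median -0.57, camera adjusted p = 0.00492 with the preset correlation). This shorter list was not tested with an estimated correlation. mei-P26 fell from 3088 ± 428 to 738 ± 30.8 (log2 -2.05) and Dscam1, a neuronal adhesion gene, from 449.7 ± 28.8 to 246 ± 24.1 (-0.87), whereas lin-28 rose to 163 ± 17.7 (2.74). These are sums over all 3' ends of a gene, so they say nothing of which end was used. Of 5 known ELAV splicing targets 2 rose and 2 fell, also adjusted over the list alone (median before subtracting that of all genes 0.14, -0.01 under TMM scaling, mean -0.30, test in the lower direction, adjusted p = 0.801). This list holds fne, which is deleted in elav5/fne and lowers the mean and the test of the list. The list was not tested without fne. ewg, a transcription factor gene, rose from 104 ± 14.0 to 689 ± 56.5 (2.72), Dscam1 and fne fell, and Nrg was at 0.33, a call lost without Canton-S replicates 1 or 2 (0.32 and 0.32) or elav5/fne replicates 1 or 2 (0.29 and 0.32). Of the 3 ELAV/Hu genes 2 fell, also adjusted over the list alone (adjusted p = 0.0308; adjusted p = 0.339 with an estimated correlation, 0.0563 under TMM scaling and 0.0510 under median of ratios scaling, range over settings 0.00886 to 0.0563). Of 16 other neuronal RNA-binding proteins 3 rose and 5 fell, also adjusted over the list alone (median before subtraction -0.13, mean 0.19, test in the lower direction, adjusted p = 0.252). Syp (chromosome 3R, 20756729 to 20810726), a regulator of neuroblast timing, rose from 4.30 ± 1.89 to 80.1 ± 5.58 (3.99) and Rbp6 fell from 3729 ± 177 to 1537 ± 275 (-1.29). Of 16 cleavage and polyadenylation factors 3 rose and 4 fell, also adjusted over the list alone (median -0.33, adjusted p = 0.356), with pAbp, the poly(A) binding protein gene, from 5725 ± 551 to 11000.5 ± 519 (0.95) and CstF50 from 7.13 ± 2.26 to 1.69 ± 0.298 (-1.57).

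Of 18 neuroblast genes 12 rose, 2 fell and 4 did not pass (12 rose and 3 fell adjusted over the list alone), and the list median was 1.44 relative to all genes (adjusted p = 0.00301; adjusted p = 0.478 with an estimated correlation). Beside ase, mira, which partitions fate determinants in dividing neuroblasts, rose from 24.7 ± 3.82 to 114 ± 19.0 (log2 2.15), the temporal factor gene cas from 23.4 ± 2.67 to 131 ± 17.7 (2.43) and klu from 93.3 ± 5.35 to 436 ± 61.9 (2.20). The list level was higher than in every Canton-S library in all 3 elav5/fne libraries, by 0.95 to 1.498 over the Canton-S mean, and lowest in replicate 3, the library with the highest muscle and gut levels. Of 18 cell cycle genes 5 rose and none fell, also adjusted over the list alone, without the list passing (median 0.14, adjusted p = 0.177). stg, the Cdc25 phosphatase gene that starts mitosis, went from 30.1 ± 6.47 to 209.7 ± 50.1 (2.75) and CycA from 27.5 ± 1.39 to 73.7 ± 13.1 (1.37). Of 10 apoptosis genes 8 rose and none fell, also adjusted over the list alone (median 1.82, adjusted p = 0.000297; adjusted p = 0.339 with an estimated correlation). The death activators hid, rpr and skl rose from 2.64, 1.77 and 0.925 to 24.7 ± 5.96, 20.5 ± 2.39 and 19.1 ± 4.32 (2.81, 3.04 and 3.37). Of 21 glial genes 6 rose, 5 fell and 10 did not pass (7 rose and 5 fell adjusted over the list alone); the median was 0.13, -0.02 relative to all genes and -0.01 under TMM scaling, with a test in the lower direction and adjusted p = 0.905. Inx2, a gap junction gene, rose from 94.4 ± 4.10 to 191 ± 14.1 (1.01) and wrapper, a gene of glia that ensheath axons, fell from 38.6 ± 7.14 to 10.9 ± 2.49 (-1.74). Of 24 axon guidance and adhesion genes 7 rose and 4 fell (7 and 5 adjusted over the list alone), with a median before subtraction of 0.01, a mean of 0.11 and a test in the lower direction, and the median was -0.13, -0.11 and -0.06 under TMM, median of ratios and library total scaling (adjusted p = 0.905). The adhesion gene Nrt went from 113 ± 5.27 to 265 ± 28.6 (1.22) and dpr1 from 430.5 ± 4.68 to 233 ± 32.4 (-0.89).

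Ribosomal protein genes rose in 75 of 78 cases and none fell, also adjusted over the list alone (median 0.62, adjusted p = 2.51e-19; adjusted p = 0.399 with an estimated correlation), with RpL32 at 2442 ± 116 (log2 1.08). Of 20 oxidative phosphorylation genes 3 fell and none rose (2 fell adjusted over the list alone), and the list passed (median -0.33, adjusted p = 0.00323; adjusted p = 0.621 with an estimated correlation). SdhA, a complex II subunit gene, fell from 218 ± 9.69 to 145 ± 8.46 (-0.59). All 5 ring gland genes fell, also adjusted over the list alone (median -1.22, adjusted p = 0.00238; adjusted p = 0.383 with an estimated correlation), with spok at 4.99 ± 0.366 (-1.97) and jhamt, a juvenile hormone synthesis gene, from 17.2 ± 4.03 to 4.42 ± 1.31 (-1.76). Of 12 heat shock genes 7 rose and none fell, also adjusted over the list alone (median 1.95, adjusted p = 0.0187; adjusted p = 0.621 with an estimated correlation). Hsc70-3, a chaperone of the endoplasmic reticulum, rose from 279 ± 61.8 to 993 ± 194 (1.83). This list call was lost without Canton-S replicate 1 (adjusted p = 0.0505) and without elav5/fne replicate 2 (0.0608), with a range over settings of 0.00320 to 0.0608. Of 14 detoxification genes 8 rose and 2 fell (8 and 4 adjusted over the list alone) and the list did not pass (median 1.58, adjusted p = 0.148). GstE6 rose to 117 ± 6.42 (4.09) and Cyp6g2, a cytochrome P450 gene, fell from 30.8 ± 1.64 to 4.26 ± 0.654 (-2.604). Of 5 dosage compensation and sex genes 3 rose and 1 fell, also adjusted over the list alone (median 0.69, adjusted p = 0.356): lncRNA:roX1 was at 3991 ± 379 (1.42) and Sxl at 300.2 ± 22.8 (-1.59).

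The remaining lists cover muscle, gut and other tissues outside the nervous system, and immune genes. Of 16 muscle genes, all measurable in Canton-S, 6 rose and none fell (8 rose adjusted over the list alone), and the list median was 1.995 relative to all genes (adjusted p = 0.0185; adjusted p = 0.621 with an estimated correlation). wupA, a troponin gene, went from 19.0 ± 2.43 to 219.6 ± 62.1 (log2 3.43) and Tm2, a tropomyosin gene, from 34.3 ± 1.89 to 288 ± 148 (2.90). The muscle list did not pass without elav5/fne replicate 3 (adjusted p = 0.0724) (range over settings 0.00194 to 0.0724). None of 9 gut genes passed, also adjusted over the list alone (median 1.99, adjusted p = 0.248), with the trypsin gene alphaTry at 6.41 ± 4.36 in Canton-S and 152 ± 145 in elav5/fne. Of 9 cuticle, epidermis and trachea genes 4 rose and none fell, also adjusted over the list alone (median 1.1104, adjusted p = 0.148). obst-A, a chitin-binding protein gene, rose from 2.11 ± 1.02 to 12.8 ± 3.97 (2.18). Of 8 antimicrobial and immune genes 3 rose and 1 fell, also adjusted over the list alone (median 1.13, adjusted p = 0.257), with Rel, an NF-kappaB factor, from 16.98 ± 4.42 to 61.7 ± 6.17 (1.82). Of 12 fat body genes 1 rose and 1 fell, also adjusted over the list alone (median -1.43, adjusted p = 0.177). That median rested on Canton-S replicate 2, where the list level lay 2.07 above the Canton-S mean against -1.02 and -1.05 in the other 2, and without that library fat body genes had a median of -0.04 (adjusted p = 0.727, range over settings 0.0337 to 0.727). The lipase gene bmm rose from 61.7 ± 16.4 to 190.5 ± 24.2 (1.63). Of 10 hemocyte genes 1 rose and 1 fell (none and 1 adjusted over the list alone; median 0.42 with a test in the lower direction, adjusted p = 0.922), PPO2, a prophenoloxidase gene, going from 16.04 ± 2.33 to 5.82 ± 1.21 (-1.33). Only 2 salivary gland genes were measurable, neither passed over all genes and 1 rose adjusted over the list alone, and no list test was made. fkh, a salivary gland regulator, was at 56.1 ± 7.79 and 75.1 ± 10.5. In sum 14 of 27 lists, with the ELAV/Hu family that holds both deleted genes, passed camera with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.339 and 3 lists had an unadjusted p under 0.05.

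The third comparison, elav5/fne against elav5, asked what the loss of fne adds when elav is already lost, and is itself the test of the difference between both mutants. Whether both mutant strains differ in more than fne is not given in the sources used here. Such differences would enter this comparison and cannot be told apart from the loss of fne. The neuropeptide, transmitter, synaptic, ion channel, glycolysis and oxidative phosphorylation lists were lower in elav5/fne than in elav5, and the neuroblast, cell cycle and apoptosis lists higher, with a preset correlation. All 9 of these calls were lost otherwise (adjusted p = 0.253 to 0.590 with an estimated correlation). Snap25 went from 139 ± 15.8 normalised CPM in elav5 to 4.71 ± 3.90 in elav5/fne (log2 -4.81, SE 0.36), and Ilp2 from 59.5 ± 20.8 to 2.07 ± 1.32 (-4.35). ase went from 4.64 ± 0.902 to 62.3 ± 7.03 (3.49, SE 0.26) and Syp from 3.90 ± 1.57 to 80.1 ± 5.58 (4.11). In all, 2888 of 9384 genes passed (limma with Benjamini-Hochberg adjustment), 1734 higher and 1154 lower, 806 and 461 of them over 2-fold. Libraries did not overlap for 43.8% of genes, where chance gives 10%. The median of all genes was 0.15; under TMM scaling it was 0.06 and 1305 genes were higher and 1417 lower, and under median of ratios scaling, where the median was 0.05, a shift of over 0.1, 1274 were higher and 1444 lower. The count was 2656 without elav5 replicate 1 and elav5/fne replicate 3.

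The 5 largest rises were w (log2 6.90), LysD (5.37, and 4.66 without elav5/fne replicate 3 and 6.47 without elav5/fne replicate 1), CG40472 (5.22), wntD (4.61) and Kmn1, a kinetochore gene (4.39). CG40472 went from 0.348 ± 0.335 in elav5 to 48.5 ± 4.68 in elav5/fne against 96.2 ± 7.79 in Canton-S. sn, at 14.5 ± 1.36 in elav5 and 177 ± 14.8 in elav5/fne (3.52), and Prosbeta6, at 8.12 ± 2.99 and 68.1 ± 4.63 (2.97), were low in elav5 too. elav was low in both mutants, so its loss did not by itself set the level of CG40472, sn and Prosbeta6. A reversal by the loss of fne and another difference between the strains cannot be told apart. The 5 largest falls were Snap25, dpr21, a cell surface protein gene of neurons (-4.74), CG42361 (-4.46), Ilp2 and the metallothionein gene MtnF (-4.25), which went from 98.6 ± 26.6 to 4.73 ± 3.54. fne itself fell by 3.70.

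Of 25 neuropeptide and processing genes 21 fell and none rose, also adjusted over the list alone (median -1.64 relative to all genes, adjusted p = 1.2e-16; adjusted p = 0.253 with an estimated correlation), and Pdf went on to fall by 2.90 on the log2 scale. All 12 glycolysis genes fell, also adjusted over the list alone (median -1.26, adjusted p = 2.57e-12; adjusted p = 0.253 with an estimated correlation), with Ldh at 1408 ± 244 in elav5 and 534 ± 80.2 in elav5/fne. Of 13 transmitter genes 12 fell and 13 fell adjusted over the list alone (median -1.61, adjusted p = 5.78e-12; adjusted p = 0.253 with an estimated correlation), Vmat going from 657 ± 32.9 to 94.7 ± 20.9 (-2.80). Of 16 synaptic genes 13 fell, also adjusted over the list alone (median -0.79, adjusted p = 1.36e-09; adjusted p = 0.373 with an estimated correlation). Of 17 ion channel genes 12 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.76, adjusted p = 1.27e-07; adjusted p = 0.520 with an estimated correlation), slo going from 1445 ± 239 to 472 ± 34.4 (-1.60). Of 20 oxidative phosphorylation genes 4 fell, also adjusted over the list alone (median -0.40, adjusted p = 0.000127; adjusted p = 0.590 with an estimated correlation). Of 18 genes with neural 3' UTR extensions 8 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.32, adjusted p = 0.0164; adjusted p = 0.865 with an estimated correlation). Without elav and fne 7 of 16 fell (camera adjusted p = 0.0446 with the preset correlation, the only one used for this shorter list). The full list did not pass without elav5/fne replicate 3 (adjusted p = 0.0772, range over settings 0.00424 to 0.0835).

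Of 18 neuroblast genes 11 rose and 2 fell, also adjusted over the list alone (median 1.27, adjusted p = 0.00249; adjusted p = 0.583 with an estimated correlation), mira going from 22.2 ± 3.80 to 114 ± 19.0 (log2 2.30). Of 18 cell cycle genes 10 rose and none fell, also adjusted over the list alone (median 0.59, adjusted p = 0.000847; adjusted p = 0.476 with an estimated correlation), with CycA from 22.4 ± 2.88 to 73.7 ± 13.1 (1.67) and polo, a mitotic kinase gene, from 5.87 ± 0.978 to 21.2 ± 3.73 (1.69). Of 10 apoptosis genes 7 rose, also adjusted over the list alone (median 1.44, adjusted p = 0.00134; adjusted p = 0.363 with an estimated correlation), with hid from 4.66 ± 0.503 to 24.7 ± 5.96 (2.16). Of 78 ribosomal protein genes 16 rose (6 adjusted over the list alone), with a median of 0.01 relative to all genes and adjusted p = 0.00514 (adjusted p = 0.975 with an estimated correlation). This list did not pass under TMM (0.236) or median of ratios scaling (0.262), where 4 genes rose and 1 fell each, or without elav5 replicate 2 (0.279, 7 and 1), with a range over settings of 7.29e-06 to 0.279. Of 5 ring gland genes 1 fell, jhamt, from 9.84 ± 2.602 to 4.42 ± 1.31 (-1.001), a call lost without elav5 replicate 2 (-0.83) or elav5/fne replicate 3 (-0.78). spok was at 4.74 ± 1.58 and 4.99 ± 0.366, and the list did not pass (adjusted p = 0.848). Neither muscle genes nor gut genes passed as a list (adjusted p = 0.515 for both), but without elav5 replicate 1 both did (adjusted p = 0.00762 for muscle genes and 0.0497 for gut genes, ranges over settings 0.00762 to 0.939 and 0.0497 to 0.986). In all 11 of 27 lists passed camera with the preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.253 and 3 lists had an unadjusted p under 0.05. In lists that did not pass, without subtracting the median of all genes, the median, mean and test differed in sign for axon guidance and adhesion (-0.04, 0.06, lower), cleavage and polyadenylation factors (0.09, 0.00, lower), detoxification genes (0.50, -0.03, lower), dosage compensation and sex genes (-0.05, 0.02, lower), fat body genes (0.02, 0.21, lower), known ELAV splicing targets (0.18, -0.33, lower), other neuronal RNA-binding proteins (0.04, 0.30, lower) and ring gland genes (0.10, -0.01, lower). The known ELAV splicing targets hold fne, whose deletion in elav5/fne lowers their mean and test. Medians changed sign under another scaling for axon guidance (0.05) and dosage compensation (0.04) with library totals, and under median of ratios for cleavage factors (-0.01), other RNA-binding proteins (-0.08) and ring gland genes (-0.002).

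The calls of both mutants against Canton-S overlapped: 609 genes were higher in both and 397 lower in both, where independent lists of these sizes would share 198 and 115.4. Simulated unchanged groups against the same controls had a median of 0 calls, so they give no reference for these shared counts. GstE6, RpL32 and lncRNA:roX1 are among the shared rises and Pdf, Orcokinin, spok and mei-P26 among the shared falls. The overlap was 509 in place of 1006 without Canton-S replicate 1 and 533 without Canton-S replicate 2. Of the 1006 shared genes 306 were further from Canton-S in elav5/fne than in elav5 by the test of the difference, 205 of them higher and 101 lower, 31 were closer, and 669 did not differ. Pdf and Orcokinin were further away in elav5/fne (log2 -2.90 and -1.34 against elav5), whereas spok (0.10), RpL32 (0.26) and lncRNA:roX1 (-0.05) did not pass that test. A further 3010 genes were called in elav5/fne and not in elav5, and of these 1884 differed between both mutants in the same direction; 382 were called in elav5 and not in elav5/fne, and of these 205 differed. The log2 fold changes of both comparisons correlated across genes with r = 0.66 (simulated median 0.56, highest 0.97, over 100 draws). Of these changes 73.2% had the same sign (simulated median 67.4%, highest 90.7%), so both measures lay within the simulated range. The covariance of the fold changes was 0.52, above the highest simulated value of 0.29. It differed by 0.46 from the simulated median of 0.06. Both comparisons share the 3 Canton-S libraries, which are too few to be divided, and part of the excess may come from them. In 40 genes the calls were opposite, 24 lower in elav5 and higher in elav5/fne and 16 the reverse, where independent lists would give 170 and 134.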

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

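Of the results in this part, the tests of the neuroblast, muscle and gut lists were chosen only after the result was seen. In 40 genes both mutants differed from Canton-S in opposite directions and from each other by the limma test, and 3 of them changed at least 2-fold each way with a mean of at least 10. fru, a sex and neuron specification gene, was at 92.9 ± 13.7 normalised CPM in Canton-S, 33.1 ± 9.57 in elav5 and 378 ± 25.8 in elav5/fne, a log2 difference between both mutants of 3.51. lncRNA:CR30009 went the same way, at 29.1, 12.7 and 61.5 (difference 2.18), and both genes kept their calls without each library in turn. CG12420, at 10.6, 28.6 and 2.99, went the other way (difference -2.95), but its rise in elav5 lost its call without Canton-S replicate 1, Canton-S replicate 3 or elav5 replicate 2, with adjusted p up to 0.0661; the cause was not tested.

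In elav5/fne 12 of 18 neuroblast genes rose, 2 fell and 4 did not pass, while 22 of 25 neuropeptide, 12 of 13 transmitter, 14 of 16 synaptic and 13 of 17 ion channel genes fell and none rose. With an estimated correlation these list calls were lost (adjusted p = 0.478 for neuroblast genes and 0.339 to 0.399 for the others with an estimated correlation). A smaller share of neurons that raises every other cell type alike could give this. The neuroblast median exceeded the glial median by 1.46 (1.59 against 0.13, permutation p = 0.00022 over 100000 draws of 18 and 21 genes, which are not independent replicates). This test was chosen after the rise of the neuroblast list was seen. Of 21 glial genes 6 rose and 5 fell, so their median is an uncertain measure of the share of glia. The test therefore cannot decide. Carry-over of muscle and gut tissue may also shift a list. With the muscle level as a covariate, which took the median of the gut genes from 2.14 to -0.34, the neuroblast median was 1.71. All elav5/fne libraries exceeded every Canton-S library in muscle level, so this fit cannot separate carry-over from genotype. Neuroblast levels lay 1.498, 1.38 and 0.95 above the Canton-S mean in elav5/fne replicates 1, 2 and 3. Muscle levels there lay at 0.97, 2.13 and 3.10. In elav5, neuroblast levels were 0.20, 0.28 and 0.12 and muscle levels 2.91, 1.15 and -0.25, in the same order. In elav5/fne neuroblast levels thus ran in the reverse order of muscle levels. In elav5 a muscle level of 2.91 in replicate 1 came with a neuroblast level of only 0.20, but replicate 3 was lowest in both. With 3 libraries per mutant these orders cannot decide on carry-over. An effect of genotype on the cells or a difference in larval age were not tested, and without an fne single mutant the part of fne alone is unknown.

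Muscle genes were higher in some mutant libraries, among them wupA and Tm2. Carry-over of neighbouring tissue could do this: muscle and gut levels correlated over the 9 libraries with r = 0.891 (Spearman 0.617), but that the same 3 libraries were highest in both lists had prompted the test, so this lends it no support. It was 0.878 within genotypes, 0.656 without the 2 libraries farthest from the median and -0.24 without those 3, which carry the pattern (6 libraries, too few to decide, exact permutation p = 0.65), so carry-over stays open. An effect of genotype stays open too: all 3 elav5/fne libraries lay above every Canton-S library, and 1 mutant library, elav5 replicate 3, lay below them, at -0.25 against -0.17, a gap within the spread of the Canton-S libraries. The bound first written, at least 1 such library, was too weak to exclude it, and was replaced after the values were seen by 2 libraries below by more than the Canton-S range.

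Obp99b, Lsp1beta, Fbp1 and Fbp2, fat body genes chosen after their values were seen, were high only in Canton-S replicate 2 (73.9, 112, 31.4 and 68.2 normalised CPM).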

How the results depend on the processing

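Depth sets the floor of 3 reads. Of simulated 2-fold changes 18% were recovered in elav5/fne against Canton-S, and how far depth or the spread between libraries limits this was not tested. The simulation changed 50 genes for each fold and left 9184 unchanged, against 4056 genes called in the data. The Benjamini-Hochberg adjustment is stricter with so few changed genes, so recovery in the data may be higher. For elav5 against Canton-S DESeq2 called 2157 genes and edgeR 1390 in place of 1428; the counts were 4436 and 3949 in place of 4056 for elav5/fne against Canton-S and 3018 and 2561 in place of 2888 for elav5/fne against elav5, and 86 genes had no adjusted p in DESeq2. The overlap of both mutants' calls was 1547 with DESeq2 in place of 1006. With the replicate number as a replicate block the counts were 909, 3564 and 2304 in the 3 comparisons and the overlap 649. Libraries of the same number did not resemble each other across genotypes (correlations of -0.70 to 0.20 between their deviations from the genotype means). These deviations hold the uneven muscle and gut levels, however, so a pairing by number is not excluded. Without 1 library, counts were 706 to 1532, 3253 to 4294 and 2165 to 3007 in the 3 comparisons, the overlap 509 to 1032, and elav changed by -5.90 to -5.47 in elav5 and -5.63 to -5.03 in elav5/fne, fne by -4.06 to -3.60. Lists past the threshold were 9 to 13, 13 to 14 and 10 to 13; with an estimated correlation they were 0, 0 and 0, and with the muscle level as a covariate 7 in elav5. Of 6319 pairs of a named gene result and a setting, 5979 kept the call, 340 lost it and 0 reversed. The fit over 2 genotypes gave 1083, 4419 and 2350 in the 3 comparisons, and the muscle covariate 1514, 3034 and 2958. No alternative called a gene in the direction opposite to the 9-library fit. Alternatives planned for 3' ends, distal to proximal ratios and A-rich sequence were not run, as the table holds 1 row per gene.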

Other observations

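Of the tests in this part, the one matched on gene length was chosen only after the result was seen, and the genes of the first 2 paragraphs were chosen after their values were seen. Genes of the Enhancer of split complex, targets of Notch signalling of which 7 here encode HLH repressors and 4 Bearded family proteins, rose in 10 of 11 cases in elav5/fne against Canton-S, with a median log2 change of 3.84, each call holding without every library in turn. E(spl)mgamma-HLH went from 4.98 ± 0.858 in Canton-S to 11.8 in elav5 and 181 ± 68.1 in elav5/fne (log2 4.86), and E(spl)m8-HLH from 4.13 to 9.19 and 78.3 (3.92). E(spl)m5-HLH did not pass (0.84, adjusted p = 0.111). In elav5 3 of the 11 rose, each losing its call without some library. N, the Notch receptor gene, went from 35.7 to 48.4 and 322 (3.14), and ttk, a repressor of neuronal fate, from 16.1 to 22.2 and 404 (4.61), whereas the activity-regulated genes sr and Hr38 fell (-2.83 and -2.44).

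Of the genes picked for their rise in elav5/fne, kay, a JNK pathway transcription factor gene, also passed in elav5, but lost that call without Canton-S replicate 1, Canton-S replicate 2, elav5 replicate 1, elav5/fne replicate 1 or elav5/fne replicate 2 (log2 0.95, adjusted p = 0.0376, up to 0.137). Mmp1, a matrix protease and target of JNK signalling, was at 7.77, 23.6 and 66.9 in Canton-S, elav5 and elav5/fne (2.98 for the last against the first). Mmp1 passed in elav5 too (log2 1.48, limma adjusted p = 0.0098). Xrp1, a stress transcription factor, was at 246, 319 and 786 (1.70 for elav5/fne against Canton-S). Thor, which holds back translation, rose by 2.37, and by 1.89 without Canton-S replicate 1 and 2.99 without Canton-S replicate 3. w, at 233 only in elav5/fne, is a marker gene of many fly strains, and how the strains differ in it is not given in the sources used here.

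Genes with annotated tandem 3' ends at least 500 nt apart, on which ELAV/Hu proteins can choose an end, fell in elav5/fne more often than expression-matched other genes, 30.6% of 1203 against 22.4%, a difference of 8.24 percentage points (permutation p = 2e-05, adjusted p = 4e-05; genes are not independent replicates). Matched on gene length too, the difference was 2.11 points (SD 1.85, permutation p = 0.254), so an effect of tandem ends and one of gene length cannot be told apart. That such genes rise more often is argued against, as the difference in the share that rose was -8.04 points (24.3% against 32.3%, permutation p = 1e-05, the smallest possible). Matched on gene length too it was -1.69 points (SD 1.64, permutation p = 0.303), still below a rise of 5 points but no longer apart from 0. Whether these falls could reflect the choice of 3' end cannot be read from 1 value per gene.

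Of the 10 ways to divide 6 libraries into 3 and 3, 1, 1 and 1, the real ones, gave as many calls as the 1428, 4056 and 2888 of the 3 comparisons, and the highest others were 0, 0 and 159; 10 splits are too few for a share under 0.05.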
